A study of Mus musculus with 8 samples.

How the data were processed

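Brain cells of male C57BL/6J mice aged 8-9 weeks were profiled after transient occlusion of the middle cerebral artery and reperfusion. Per the labels' protocols, brains were perfused with cold saline, split by hemisphere, dissociated with enzymes, cleared of myelin on Percoll, stained with a Zombie viability dye and sorted for live cells, and libraries were made with a 10x Genomics 3' kit. The deposited values are whole-number UMI counts per gene and cell in 8 libraries, with no normalization. Cell Ranger, Seurat and the mouse build mm10 are named in the submitters' processing notes, without versions or the role of each tool. The deposited counts had already been filtered: every cell had over 200 detected genes, over 500 UMIs (lowest 501) and under 20% mitochondrial UMIs (highest 19.9%), as seen from the values. Such a floor takes out cells with little RNA first, neutrophils among them.

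The tables held 39945 cells, 436780956 UMIs and 20340 genes, of which 219 had no count. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept (39608; 337 were left out). Doublets were scored in each library with simulated doublets in the manner of Scrublet, and the top-scoring 0.8% per 1000 cells were left out (1583 cells, 4.0% of those kept), leaving 38025 cells. The cells used per contralateral library were 4561 (WT, 24 h), 4984 (Prdx1-/-, 24 h), 4019 (WT, 48 h) and 4170 (Prdx1-/-, 48 h). The cells used per ipsilateral library were 5080, 5441, 4926 and 4844 in the same order. Counts were scaled to 10000 per cell and log-transformed. All libraries were clustered together without integration (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9; 2000 variable genes without Prdx1, 30 principal components, 15 neighbours, Leiden resolution 1.0, seed 0). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

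A cluster took the name of the class whose fixed marker list scored highest, when at least 3 of its markers were detected in at least 10% of cells, the score was at least 1.5 times the next, its leading 10 genes did not hold more markers of another class and under 50% of its cells were doublets. A shallow cluster also needed a marker of its class among its leading genes. These rules were set after the clusters were seen, and a cluster that failed any of them stayed unnamed. Names end in "-like" because no sort marker is given in the labels.

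The marker lists, 23 gene lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. Raw counts were summed per library over the cells of a class and fitted with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16, R 4.3.3; robust, TMM scaling, filterByExpr; adjusted p under 0.05). With 1 library per combination of genotype, hemisphere and time, no group had a replicate. The libraries of the other factor levels served as replicates in an additive fit of hemisphere, genotype and time, so that effects that differ between levels add to the spread. The p-values measure variation between these libraries and not between animals. Genotype within the ipsilateral hemisphere, its interaction with hemisphere, and time within the ipsilateral hemisphere were contrasts of fits over all 8 libraries. Classes were tested with at least 20 cells in every library fitted, which left B-like cells to the 4 ipsilateral libraries. Class shares were tested by edgeR on cell counts, for classes with at least 50 cells in all.

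Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, lists of at least 4 tested genes). Camera with an estimated correlation and fry were run beside it. Fry's p-value tests whether a list's genes move one way on balance and does not compare the list with other genes. The lists were homeostatic microglia, disease and stroke associated microglia, cytokine, chemokine and NF-kB, interferon response, NRF2 targets, other antioxidant enzymes, proliferation, glycolysis and hypoxia, oxidative phosphorylation, antigen presentation, lipid and cholesterol handling, lysosome and phagocytosis, complement, dissociation and immediate-early, and reactive astrocyte, endothelial activation and blood-brain barrier genes. Transcripts of neutrophils, monocytes and macrophages, erythrocytes (hemoglobin), endothelium, oligodendrocytes and astrocytes completed them. List medians in counts of members are from edgeR fold changes.

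Named genes were those past the threshold with a mean of at least 20 CPM and the same sign in every matched pair of libraries. Of these, the 8 largest in each direction (4 in classes other than microglia-like) were named, without mitochondrial and hemoglobin genes. Up to 4 members per list with the smallest p were added, and the 3 smallest p in each direction where fewer than 3 genes passed. Prdx1 was examined in every library first. The share of cells with a Prdx1 UMI was taken after thinning each cell at random to 5000 UMIs, with 95% exact binomial intervals. Gene positions are from GENCODE M21 (GRCm38).

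The tests were checked on simulated counts of microglia-like cells with 200 changed genes, drawn from those with a mean of at least 20 CPM. Otherwise all libraries shared the same mean per gene, without differences between hemispheres, times or clusters. The recovery below therefore need not hold for the real data or for genes of lower level. Of 100 genes changed by a log2 of 1, 99 (hemisphere), 96 (genotype), 95 (genotype, ipsilateral), 66 (interaction) and 90 (time) were called, and false calls were 10.4%, 5.31%, 10.1%, 7.30% and 9.09% of calls. The alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter cell filter (500 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolution 2.0, class by marker score, thinned sums, blocks of libraries, the ipsilateral libraries alone and each library left out. For shares they also included limma on the logit of the share (0.5 added to each count), and for lists only genes of at least 20 CPM. Genes of classes other than microglia-like were not tested under Leiden resolution 2.0, class by marker score, thinned sums or blocks of libraries. Analysing the 48 h libraries alone was added after seeing the data, because Prdx1 was present at 24 h in the libraries labelled Prdx1-/-.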

Results

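Single-cell RNA sequencing was applied to brain cells of male C57BL/6J mice after transient middle cerebral artery occlusion, a stroke model in which a suture inside the vessel blocks the blood flow and is later withdrawn. The design addressed how brain immune cells respond to stroke and whether the response depends on Prdx1, which encodes peroxiredoxin 1, a cytosolic enzyme that removes hydrogen peroxide. The 8 libraries covered every combination of labelled genotype (WT or Prdx1-/-), hemisphere (ipsilateral or contralateral to the occlusion) and time (24 h or 48 h), with 1 library per combination. Nothing in the labels says how many animals went into a library, so the p-values measure only the spread between these libraries, which may be technical. The contralateral libraries held 39433266 UMIs (WT, 24 h), 47888533 UMIs (Prdx1-/-, 24 h), 43459828 UMIs (WT, 48 h) and 44441551 UMIs (Prdx1-/-, 48 h) as deposited. The ipsilateral libraries held 62580490 UMIs (WT, 24 h), 70111421 UMIs (Prdx1-/-, 24 h), 65487793 UMIs (WT, 48 h) and 63378074 UMIs (Prdx1-/-, 48 h). Between 4189 and 5759 cells per library were deposited, and 38025 cells were used in all. The median depth of the cells used ran from 7148 UMIs in the contralateral 24 h library labelled WT to 12965 UMIs in the ipsilateral 48 h library labelled WT.

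Prdx1 (chromosome 4, 116685544 to 116700822 in GRCm38) was nearly absent from the 48 h libraries labelled Prdx1-/- but present in both 24 h libraries with that label. In summed microglia-like cells it stood at 6.15 CPM (contralateral) and 7.40 CPM (ipsilateral) in the 48 h libraries labelled Prdx1-/-, against 338 and 733 CPM in the 48 h libraries labelled WT. At 24 h the libraries labelled Prdx1-/- held 87.8 CPM (contralateral) and 639 CPM (ipsilateral), against 263 and 594 CPM in those labelled WT. The ipsilateral 24 h values came mostly from cluster 7. It held 14096 of 17226 Prdx1 UMIs under the label Prdx1-/- (393 of 2144 cells, 2634 CPM), and 16856 of 22584 under the label WT (1137 of 3127 cells, 1127 CPM). With each cell thinned to 5000 UMIs, 23.5% (95% exact binomial interval 22.3 to 24.8) and 37.9% (35.8 to 40.0) of microglia-like cells had a Prdx1 UMI in the 24 h libraries labelled Prdx1-/-, contralateral and ipsilateral. The same share was 3.31% (2.65 to 4.09) and 3.64% (2.17 to 5.69) at 48 h under that label. In the libraries labelled WT it was 68.8% and 56.7% at 24 h and 72.7% and 81.8% at 48 h. The intervals cover counting error only, and 40 to 489 cells per library were too shallow to thin. Under the label WT, too, the ipsilateral 24 h library held many cells without a Prdx1 UMI. In cluster 7 the thinned share was 54.5% (51.5 to 57.4) there, 67.2% in the matched library labelled Prdx1-/- and 98.2% in the ipsilateral 48 h library labelled WT. In monocyte/macrophage-like cells it was 61.7% there, against 93.7% in the ipsilateral 48 h library labelled WT. Without thinning, the microglia-like shares under the label Prdx1-/- were 28.0% and 46.4% at 24 h and 5.17% and 9.91% at 48 h, and those under the label WT were 77.8%, 67.4%, 81.6% and 90.5%. Neutrophil-like cells, low in Prdx1 under the label WT as well (20.4 to 56.0 CPM), gave thinned shares of 2.20% to 10.9% over the 8 libraries, at a median depth of 4352 UMIs against 8266 UMIs in microglia-like cells. Many were too shallow to thin, such as 1183 of 1270 in the ipsilateral 48 h library labelled WT. Only 21 were left in the contralateral 24 h library labelled Prdx1-/-. The 48 h microglia-like shares under the label Prdx1-/- lay within this neutrophil-like range, and the 24 h shares lay above it. T and NK-like cells of the 48 h libraries labelled Prdx1-/- stood at 0 CPM (contralateral) and 1.98 CPM (ipsilateral), below the microglia-like cells there. Prdx1 was thus present at 24 h under the label Prdx1-/-. In microglia-like cells it was lower than under the label WT on the contralateral side. On the ipsilateral side its share of cells was lower but its CPM was not. Every genotype direction given here is between libraries as labelled.

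**Figure D1:**
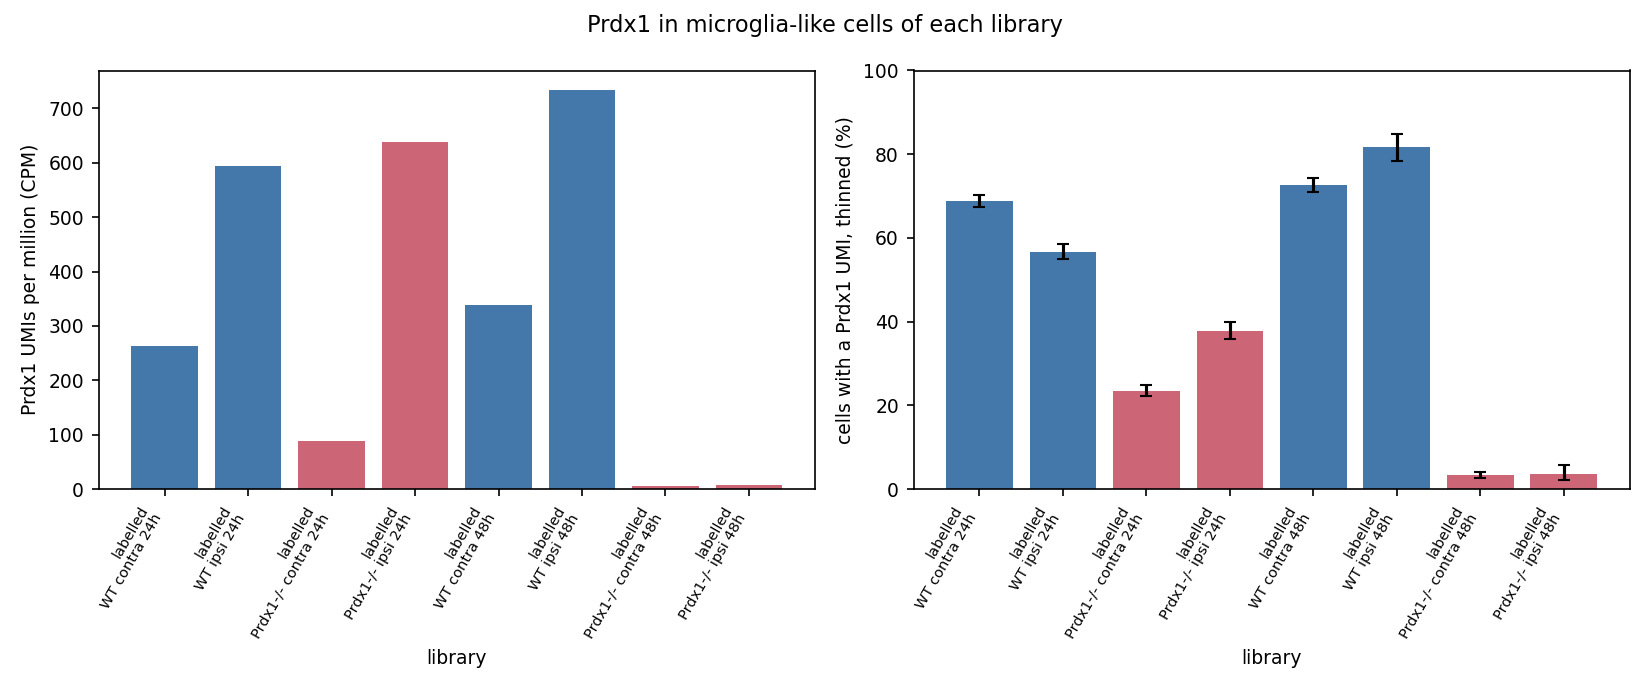
Prdx1 in microglia-like cells of each of the 8 libraries, as CPM of the summed counts (left) and as percent of cells with a Prdx1 UMI after thinning to 5000 UMIs (right), with 95% exact binomial intervals as error bars; bars are libraries, blue labelled WT and red labelled Prdx1-/-. The 24 h libraries labelled Prdx1-/- stand at 87.8 and 639 CPM, and the 48 h libraries with that label at 6.15 and 7.40 CPM.

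Clustering gave 36 clusters, of which those with enough markers of 1 class were named for it. The microglia-like class held 21123 cells. Its clusters included ones led by heat shock genes (Hspa1b, Hspa1a), by immediate-early genes (Fosb, Egr1, Fos), by cytokines (Ccl12, Tnf, Il1a) and by interferon-induced genes (Ifit3, Ifit2), and another monocyte/macrophage-like cluster was led by Rsad2 and Ifit3. The contralateral microglia-like cells lay mainly in clusters 0, 1, 5, 3 and 2 (29.4%, 25.0%, 14.96%, 14.0% and 11.1% of the class, mean of 4 libraries). The ipsilateral ones lay mainly in clusters 2, 7, 3 and 14 (36.5%, 21.3%, 17.4% and 10.5%). Cluster 7, 0.432% of the contralateral class, was led by Mmp12, Spp1, Lpl, Mt2 and Srxn1, with Prdx1 also among its leading 10 genes. It had 0 microglia markers there, as did clusters 2, 3, 5, 14 and 17 of the class, and the lowest microglia score of the class (0.102). Values within the class thus compare hemispheres in which partly different clusters held most of it.

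Monocyte/macrophage-like and neutrophil-like cells made up more of the cells from the injured hemisphere and microglia-like cells less. Monocyte/macrophage-like cells were 4.31% ± 2.76 (SD, n = 4 libraries) of contralateral and 21.0% ± 7.91 of ipsilateral cells, a log2 fold change of 2.47 (SE 0.55, adjusted p = 0.0048, edgeR quasi-likelihood test). Neutrophil-like cells went from 3.56% ± 2.72 to 25.7% ± 8.58 (log2 fold change 3.09, SE 0.62, adjusted p = 0.0045). Both classes were higher in 4 of 4 pairs of hemispheres. Microglia-like cells fell from 82.3% ± 10.3 to 31.0% ± 24.2 (log2 fold change -1.77, SE 0.59, adjusted p = 0.0438), lower in 4 of 4 pairs. In the ipsilateral libraries they were 61.6% and 39.4% of cells at 24 h (WT and Prdx1-/-) and 12.1% and 11.045% at 48 h. Of the 10 classes tested these 3 passed, while border macrophage-like cells, which express Mrc1 and Lyve1, went from 1.32% to 0.405% (adjusted p = 0.0593), lower in 4 of 4 pairs. The microglia-like call was lost without the ipsilateral 24 h library labelled Prdx1-/- (adjusted p = 0.106) or without any of the 48 h libraries (0.134 and 0.169 for WT contralateral and ipsilateral, 0.146 and 0.137 for Prdx1-/-). The border macrophage-like share passed without the ipsilateral 24 h library labelled WT (0.0357) or the contralateral 24 h library labelled Prdx1-/- (0.0041). With microglia-like cells left out of the total, the log2 fold changes were 0.34 for monocyte/macrophage-like cells (adjusted p = 0.442), 1.07 for neutrophil-like cells (0.0779) and -4.04 for border macrophage-like cells (0.0033).

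**Figure D2:**
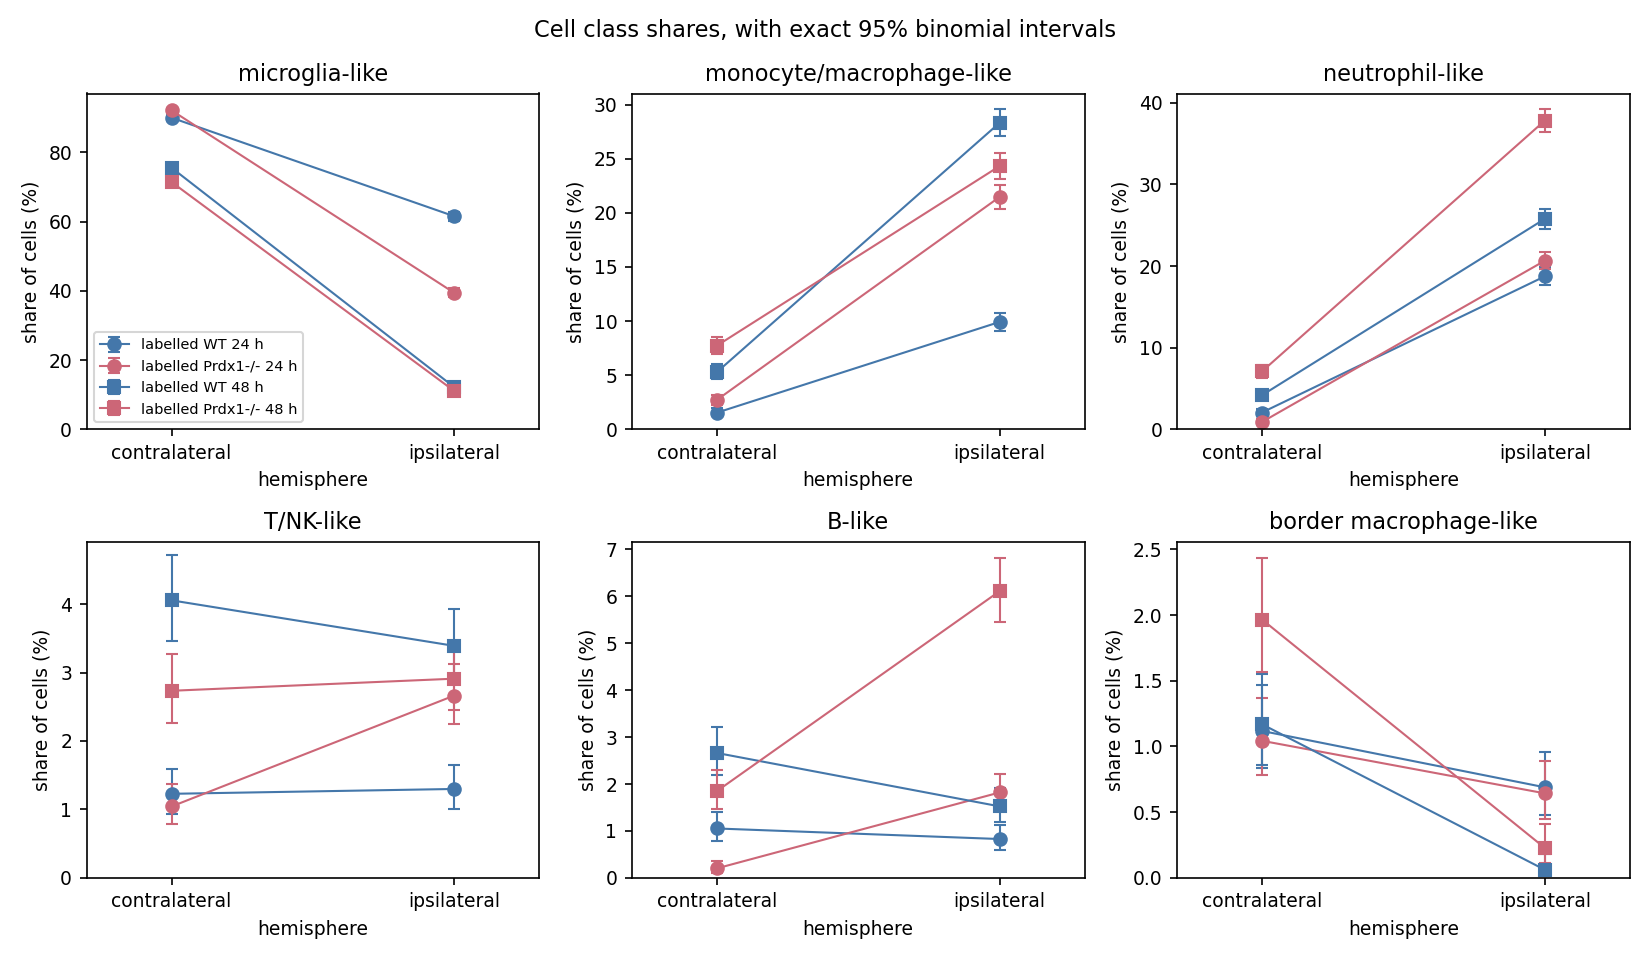
Share of cells (%) of 6 cell classes in each library, contralateral against ipsilateral, with lines joining libraries of the same labelled genotype (blue WT, red Prdx1-/-) and time (circles 24 h, squares 48 h) and 95% exact binomial intervals as error bars. Microglia-like cells are lower and monocyte/macrophage-like and neutrophil-like cells higher on the ipsilateral side in 4 of 4 pairs.

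The shares reflect what passed a density gradient (Percoll), a sort for live cells and a floor of 501 UMIs in the cells as deposited, which can take shallow cells out unevenly. Neutrophil-like cells had a median depth of 4352 UMIs against 8266 in microglia-like cells. Clusters left without a name held 2.04%, 4.94%, 1.57% and 10.2% of cells at 24 h (WT contralateral, WT ipsilateral, Prdx1-/- contralateral, Prdx1-/- ipsilateral). At 48 h, in the same order, they held 5.95%, 27.8%, 5.68% and 16.0%, and the thresholds for naming were set after the clusters were seen. With cells classed by marker score, the ipsilateral 48 h library labelled WT held 2725 monocyte/macrophage-like cells in place of 1395. The log2 fold changes between hemispheres were then 2.44 for this class (adjusted p = 0.0054) and -0.53 for border macrophage-like cells (adjusted p = 0.444). Between labelled genotypes 0 of 10 class shares passed edgeR's quasi-likelihood test, and 0 had an unadjusted p under 0.05; limma on the logit of the share also called 0. Microglia-like cells had a log2 fold change of -0.25 (SE 0.56) and monocyte/macrophage-like cells one of 0.60 (SE 0.52), both with adjusted p = 0.958.

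In microglia-like cells of the injured hemisphere, most homeostatic microglia genes were lower, and most NRF2 target, cytokine and proliferation genes were higher. Of 13318 genes tested, 3068 were higher and 3152 lower in the ipsilateral libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 4 libraries against 4), and 5914 of these moved the same way in all 4 pairs. Mmp12, Spp1 and Srxn1 were among the genes that led cluster 7, which held few contralateral cells. Mmp12 (macrophage elastase) rose by a log2 fold change of 4.97 (SE 0.80, adjusted p = 0.0096). Spp1 (osteopontin, a secreted matrix protein of reactive microglia) rose by 4.00 (SE 0.41, adjusted p = 0.0011). Between the 24 h libraries labelled WT it went from 327 to 10599 CPM, a larger step than the fitted one. Srxn1 (sulfiredoxin, which repairs over-oxidised peroxiredoxins) rose by 4.26 (SE 0.39, adjusted p = 0.0012), and Il1rn (the interleukin 1 receptor antagonist) by 4.28 (SE 0.58, adjusted p = 0.0052). Vim (vimentin), Lgals3 (galectin 3), the neutrophil-attracting chemokine gene Cxcl3 and the protease gene Adam8 rose by 3.73, 3.63, 4.87 and 3.62. The largest falls were in B430010I23Rik (-2.05, SE 0.16, adjusted p = 8.21e-05), Ddit4 (-1.76, SE 0.36, adjusted p = 0.015), the sulfotransferase gene Sult1a1 (-1.72, SE 0.15), Il16 (-1.68, SE 0.13), Agmo (-1.58), the fructose transporter gene Slc2a5 (-1.53), Gm10138 (-1.50) and Atp8a2 (-1.49). With the 48 h libraries alone, chosen after seeing the data, 3543 genes passed, and Spp1 (3.37, adjusted p = 0.121), Vim, Lgals3, Adam8 and Cxcl3 did not. Lgals3 also lost its call without 1 of 4 libraries (adjusted p = 0.0799, 0.0772, 0.0604 and 0.0527 without Prdx1-/- contralateral 24 h, Prdx1-/- ipsilateral 24 h, WT contralateral 48 h and WT ipsilateral 48 h). Adam8 lost it without either contralateral 24 h library (0.0667 WT, 0.0639 Prdx1-/-), Cxcl3 without the Prdx1-/- one (0.0604), and Ddit4 without either (0.0632, 0.062) or without Prdx1-/- ipsilateral 24 h (0.0542).

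Of the 18 homeostatic microglia genes, 17 fell and 1 did not pass, with a median log2 fold change of -1.10, and 17 were lower when adjusted over the list alone. Siglech (-1.42, SE 0.10, adjusted p = 1.98e-05), the lysophospholipid receptor gene Gpr34 (-1.41), Ltc4s (-1.18) and the microglial transcription factor gene Sall1 (-1.08) were among them, and many of the list's genes also served as markers of the class. The camera test gave adjusted p = 2.87e-08 for the list, and adjusted p = 0.371 with an estimated correlation. Of 21 tested genes of disease and stroke associated microglia, 12 rose, 3 fell and 6 did not pass (13 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.006, and adjusted p = 0.406 with an estimated correlation). Ch25h (cholesterol 25-hydroxylase) rose by 3.10 and the cathepsin gene Ctsl by 0.87, while Trem2, a lipid-sensing receptor of microglia, fell by 0.68. Of the 18 genes for cytokines, chemokines and NF-kB signalling, 13 rose, 0 fell and 5 did not pass (14 higher adjusted over the list alone; camera adjusted p = 3.33e-06, and adjusted p = 0.390 with an estimated correlation). Cxcl2 rose by 3.27, Ccl2 by 1.95, Il1a by 1.32 and Il1b by 1.13. Of the 18 interferon response genes, 8 rose and 10 did not pass (8 higher adjusted over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.406 with an estimated correlation), with Isg15 at 1.25, Ifitm3 at 0.86 and Usp18 at 0.57. Ifitm3 and Usp18 did not pass with the 48 h libraries alone (adjusted p = 0.150 and 0.225).

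Of the 19 tested NRF2 targets, genes switched on by the oxidant-sensing transcription factor NRF2, 18 rose and 1 did not pass (19 higher adjusted over the list alone), with a median of 1.23. The camera test gave adjusted p = 9.79e-08, and adjusted p = 0.313 with an estimated correlation. Txnrd1 (thioredoxin reductase 1) rose by 1.51 (SE 0.11, adjusted p = 2.44e-05), Txn1 (thioredoxin) by 1.15, Sqstm1 by 1.48 and Me1 (malic enzyme) by 3.04. Of the 17 other antioxidant genes, 10 rose and 7 did not pass (11 higher adjusted over the list alone; camera adjusted p = 8.27e-04, and adjusted p = 0.313 with an estimated correlation), among them the metallothionein gene Mt1 (1.59), Glrx (2.12), and the peroxiredoxin genes Prdx6 (0.76) and Prdx5 (0.52).

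Of the 26 proliferation genes, 22 rose and 4 did not pass (23 higher adjusted over the list alone; camera adjusted p = 2.42e-07, and adjusted p = 0.313 with an estimated correlation), with Cks1b at 0.87, Cdk1 at 0.89 and Ccnb2 at 1.18. Ccnb2 did not pass with a stricter cell filter (0.51, adjusted p = 0.343). Of the 20 glycolysis and hypoxia genes, 14 rose, 2 fell and 4 did not pass (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 8.78e-04, and adjusted p = 0.406 with an estimated correlation). Vegfa, the vascular growth factor gene, rose by 2.03, Pkm by 1.38 and Pfkp by 1.45. Of the 20 oxidative phosphorylation genes, 17 rose and 3 did not pass (18 higher adjusted over the list alone; camera adjusted p = 8.41e-07, and adjusted p = 0.371 with an estimated correlation), by smaller steps such as 0.58 for Uqcrq and 0.55 for Cox5a. Lipid genes split: 8 of 18 rose, 4 fell and 6 did not pass (8 and 4 adjusted over the list alone; camera adjusted p = 0.158), with the lipid droplet gene Plin2 at 2.41, the fatty acid receptor gene Cd36 at 2.66 and Lpcat3 at -0.45. Of 18 lysosome and phagocytosis genes, 2 rose, 7 fell and 9 did not pass (2 and 7 adjusted over the list alone; camera adjusted p = 0.0947), with Mertk, a receptor for dying cells, at -0.58, Ctsh at -0.60 and Hexa at -0.53. Of 15 antigen presentation genes, 2 rose, 6 fell and 7 did not pass (2 and 6 adjusted over the list alone; camera adjusted p = 0.667), with H2-T23 at -0.77, H2-DMa at -0.86 and H2-D1 at 0.39. Of 10 tested complement genes, 3 rose, 4 fell and 3 did not pass (3 and 4 adjusted over the list alone; camera adjusted p = 0.839), with C3 at 1.83, C5ar1 at 0.82 and C1qa at -0.52. Pfkp did not pass when each cell was classed by its marker score (0.60, adjusted p = 0.0549), nor H2-D1 with the 48 h libraries alone (0.125).

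Transcripts of other cell types moved in the same sums. Of 14 tested monocyte and macrophage transcripts 10 rose and 4 did not pass (11 higher adjusted over the list alone; camera adjusted p = 1.36e-05, and adjusted p = 0.313 with an estimated correlation), with Pf4 at 3.45, Thbs1 at 2.61 and Arg1 (arginase 1) at 2.35. Of 15 tested neutrophil transcripts 5 rose, 1 fell and 9 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.0095, and adjusted p = 0.515 with an estimated correlation), with Slpi at 2.97, Mmp8 at 2.77, Hdc at 2.53 and Csf3r, also a microglial gene, at -1.08. Without the ipsilateral 48 h library labelled Prdx1-/- the neutrophil list gave adjusted p = 0.0511. Of 10 tested endothelial transcripts 4 fell and 6 did not pass (4 adjusted over the list alone; camera adjusted p = 0.117), with the transporter gene Slco1a4 at -2.06. Of 6 tested astrocyte transcripts 1 rose and 1 fell (1 lower adjusted over the list alone; median 0.08 but a downward camera direction, adjusted p = 0.973), with the glutamate transporter gene Slc1a3 at -1.36. Of 8 tested oligodendrocyte transcripts 1 fell (1 adjusted over the list alone); their median was 0.58, while fry, unlike camera (adjusted p = 0.888), gave a downward direction (adjusted p = 0.889). Of 5 hemoglobin genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.667). Of 10 tested blood-brain barrier genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.667). Endothelial activation genes (6 of 14 tested rose, 6 adjusted over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.313 with an estimated correlation) and reactive astrocyte genes (11 of 16 tested rose, 11 adjusted over the list alone; camera adjusted p = 1.25e-04, and adjusted p = 0.313 with an estimated correlation) share Emp1 (4.94) and Timp1 (3.86), and the second also holds Stat3 (0.65). Of 18 dissociation and immediate-early genes 1 rose (Nr4a1, 1.07) and 1 fell (Jund, -0.52), with 1 and 0 adjusted over the list alone and a camera adjusted p = 0.764. When cells were classed by marker score, Arg1 (1.75, adjusted p = 0.209) and Timp1 (1.42, adjusted p = 0.0932) did not pass. Jund did not pass under 7 alternatives, 6 of them single libraries left out (adjusted p from 0.0527 to 0.152). With list genes of at least 20 CPM alone, the endothelial activation (adjusted p = 0.0698) and neutrophil lists (0.299) did not pass, and fry did not call the neutrophil list (0.0868). In all, 13 of 23 lists passed camera, 0 with an estimated correlation, and fry called 15. Fry but not camera called the lipid list higher (adjusted p = 0.0144) and the lysosome (0.0129) and endothelial transcript (0.0028) lists lower.

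**Figure D3:**
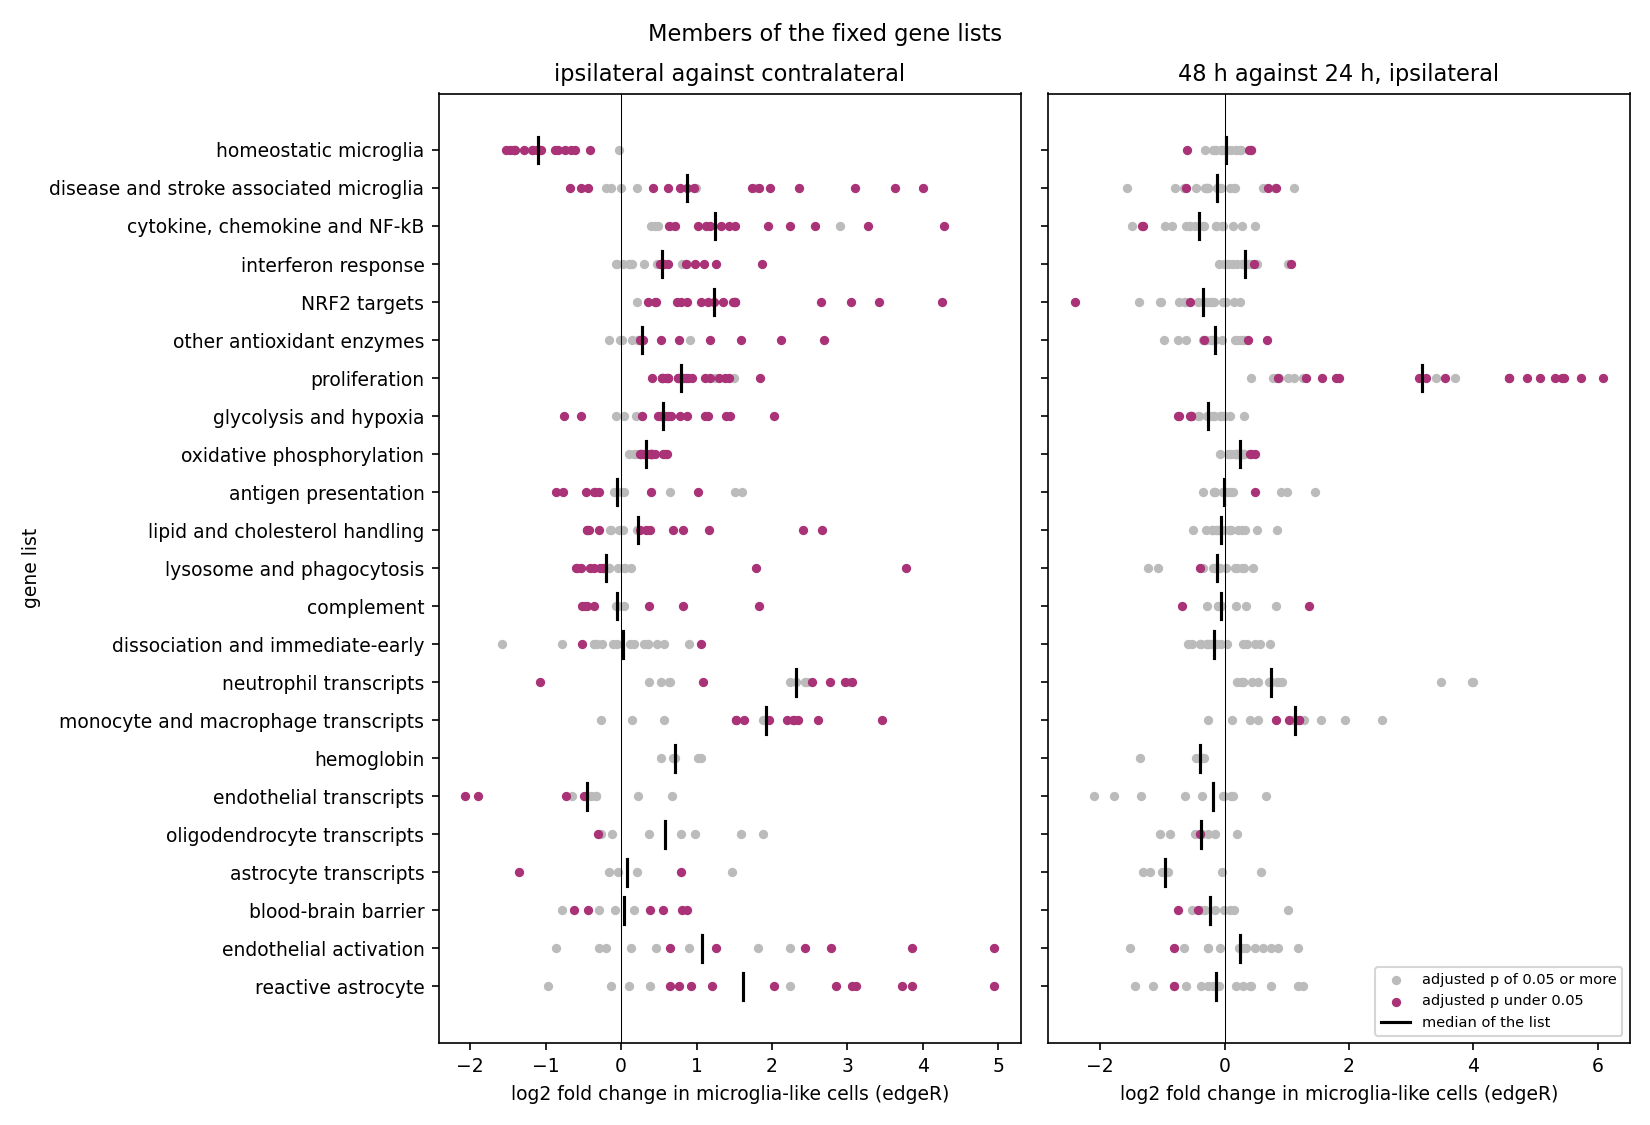
Log2 fold change in microglia-like cells of each tested member of the 23 fixed gene lists, ipsilateral against contralateral (left) and 48 h against 24 h in the ipsilateral hemisphere (right); purple points have an adjusted p under 0.05, grey points do not, and black bars are list medians. The homeostatic list has a median of -1.10 on the left and the proliferation list one of 3.18 on the right.

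Most proliferation genes were higher at 48 h than at 24 h in ipsilateral microglia-like cells. Of 13318 genes, 904 were higher and 739 lower at 48 h (edgeR quasi-likelihood test, all 1643 in the same direction under both genotype labels). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by a log2 fold change of 6.09 (SE 0.16, adjusted p = 3.92e-09), Hmmr by 5.93 (SE 0.15), the kinetochore gene Cenpf by 5.73 (SE 0.22), Birc5 (survivin) by 5.45 (SE 0.17) and Prc1 by 5.30 (SE 0.25). Mki67 (Ki-67, adjusted p = 0.0476), Top2a (0.0344) and the histone gene Hist1h1b (0.0396) rose by 5.42, 4.57 and 3.73. Of the 26 proliferation genes, 17 rose and 9 did not pass (25 higher adjusted over the list alone), with a median of 3.18, Ccnb2 at 5.32 and Cdc20 at 3.54. The contralateral libraries also held more of these transcripts at 48 h: Ube2c stood at 0.12 and 0.18 CPM at 24 h (WT and Prdx1-/-) and at 40.4 and 46.2 CPM at 48 h. Mki67 there stood at 0.33 and 1.07 CPM at 24 h and 74.2 and 82.8 CPM at 48 h. Within ipsilateral microglia-like cells, cluster 14, led by Top2a and Mki67, went from 0.831% and 0.233% of the class at 24 h (WT and Prdx1-/-) to 21.1% and 19.8% at 48 h. Cluster 7 went from 36.4% and 18.3% to 18.9% and 11.8%. The count was 792, 1003, 342 or 657 without the WT 24 h, Prdx1-/- 24 h, WT 48 h or Prdx1-/- 48 h ipsilateral library, and the calls of Mki67, Top2a and Hist1h1b were lost without most single libraries (adjusted p up to 0.209, 0.175 and 0.204). Mki67 (adjusted p = 0.260) and Top2a (0.0823) also did not pass by edgeR with the ipsilateral libraries alone. The labels do not say which libraries were prepared together, so the comparison is between libraries as labelled.

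The genes with the largest falls at 48 h were the chemokine gene Ccl9 (-1.47, SE 0.14, adjusted p = 8.74e-05), Lag3 (-1.35), the lipopolysaccharide co-receptor gene Cd14 (-1.33), Ptgs2 (cyclooxygenase 2, -1.32), B930036N10Rik (-1.28), Gdf15 (-1.27), Acvrl1 (-1.21) and Gm42418 (-1.20), which overlaps ribosomal RNA sequence and is uncertain. Of 20 glycolysis and hypoxia genes 5 fell (5 adjusted over the list alone), including the glucose transporter gene Slc2a1 (-0.74), Hk2 (-0.73), Pgk1 (-0.56) and Aldoa (-0.54). Of 19 tested NRF2 targets 2 fell (3 adjusted over the list alone), Nqo1 (-2.41, SE 0.61, adjusted p = 0.027) and Taldo1 (-0.55). Of 17 other antioxidant genes, Prdx4 (0.69, SE 0.09, adjusted p = 6.81e-04) and Sod1 (0.38) rose and Prdx6 (-0.34) fell (2 higher and 3 lower adjusted over the list alone). Of 14 tested monocyte and macrophage transcripts 4 rose (9 adjusted over the list alone), among them Lyz2 (0.83), Plac8 (1.19) and Ccr2 (1.20). Of 21 tested genes of disease and stroke associated microglia, Axl (0.83) and Apoe (0.70) rose and Cd9 (-0.62) fell (2 and 2 adjusted over the list alone). Among interferon response genes Ifit2 (1.08) rose, and of 10 tested complement genes C3 (1.36) rose and C5ar1 (-0.68) fell (3 and 1 adjusted over the list alone). Cd14, Ptgs2, Gdf15, Hk2, Pgk1, Aldoa, Nqo1, Taldo1, Sod1, Prdx6, Lyz2, Plac8, Ccr2, Axl, Apoe, Cd9, Ifit2, C3 and C5ar1 each lost the call without at least 1 library, the highest adjusted p being 0.388 (Prdx6 without the ipsilateral 24 h library labelled WT). With the stricter cell filter, Cd14, Gdf15, Hk2, Aldoa, Nqo1, Taldo1, Apoe, Sod1, Prdx6, Plac8, Ccr2 and C3 did not pass (adjusted p up to 0.292).

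Between labelled genotypes, few genes in microglia-like cells passed. Of 13318 genes, 4 were higher and 3 lower in the libraries labelled Prdx1-/- (edgeR quasi-likelihood test, adjusted p = 0.0382 for each, the same direction in 4 of 4 pairs). Slc7a5 (chromosome 8, 121881150 to 121907694), a transporter of large neutral amino acids, rose by 0.67 (SE 0.08), and Svbp (chromosome 4, 119195306 to 119201298), a partner of vasohibins, by 0.62 (SE 0.08). The other 5 lay outside the rule for named genes and were named after their values were seen: Hip1 (0.87, SE 0.11) and Relt (0.70, SE 0.09) rose, and Spata6 (-0.67, SE 0.09), Pde8b (-0.82, SE 0.11) and Tnfrsf17 (-1.37, SE 0.18) fell. Svbp and Spata6 (chromosome 4, 111719984 to 111829184) lie on the chromosome of Prdx1. Prdx1 itself had a log2 fold change of -3.13 (SE 1.80, adjusted p = 0.610), its spread set by the 24 h libraries. The class lay in partly different clusters under each label. Cluster 0, led by P2ry12 and Siglech, held 51.9% of the contralateral 24 h class under the label WT and 21.7% under Prdx1-/-. Cluster 2, led by Ccl12, Tnf and Il1a, held 28.0% and 52.7% of the ipsilateral class at 24 h and 19.1% and 46.2% at 48 h. An unadjusted p under 0.05 was reached by 1496 genes. DESeq2 called 150 genes, and edgeR called 24 without the low-count filter, 132 with a block for each hemisphere and time, and 0 with a stricter cell filter, with doublets kept or with cells classed by marker score. Leaving out 1 library gave 24 genes (without WT contralateral 24 h), 2 (without Prdx1-/- contralateral 24 h), 2 (without Prdx1-/- ipsilateral 24 h) and 0 without any of the 48 h libraries.

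In the 48 h libraries alone, where Prdx1 followed the label and had a log2 fold change of -6.19 (SE 0.20, adjusted p = 2.87e-05), 185 genes were higher and 215 lower under the label Prdx1-/-, the 7 genes above among them. This comparison was chosen after seeing the data and rests on 4 libraries and 1 residual degree of freedom. The fit over 8 libraries held these 4, so the return of the 7 genes is no separate evidence. At 48 h, clusters 5 and 1 held 9.91% and 26.9% of the contralateral class under the label WT and 26.4% and 17.8% under Prdx1-/-. Cluster 0 held 4.35% and 0.561% of the ipsilateral class. The rule for named genes did not cover this comparison, so the genes that follow are examples from its calls. How many members of each gene list rose, fell or did not pass at 48 h was not counted. The microglial genes Siglech (-0.63, adjusted p = 0.0055), Gpr34 (-0.67, adjusted p = 0.0064) and P2ry12 (-0.63, adjusted p = 0.006) and the interferon-induced gene Ifit3 (-0.82, adjusted p = 0.0043) were lower under the label Prdx1-/- at 48 h. Apoe (apolipoprotein E, 0.78, adjusted p = 0.039) and the complement gene C4b (1.15, adjusted p = 0.006) were higher. Over all 8 libraries the same genes gave -0.54 (Siglech, adjusted p = 0.101), -0.53 (Gpr34, 0.142), -0.57 (P2ry12, 0.181), -0.70 (Ifit3, 0.125), 0.63 (Apoe, 0.142) and 0.88 (C4b, 0.161), each in the same direction in 4 of 4 pairs, the 48 h pairs included.

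Of the 18 homeostatic genes 0 passed over all genes and 8 were lower adjusted over the list alone (median -0.29; camera adjusted p = 1.22e-07, and adjusted p = 0.979 with an estimated correlation). Of the 18 interferon response genes 0 passed and 7 were lower adjusted over the list alone (median -0.38; camera adjusted p = 6.32e-06, and adjusted p = 0.979 with an estimated correlation), with Ifit2 at -0.73 (adjusted p = 0.135) and Usp18 at -0.54 (0.191). Camera also called the antigen presentation list lower (0 passed, 0 adjusted over the list alone; adjusted p = 0.027). It called the cytokine list (0 and 0; adjusted p = 0.034) and the monocyte and macrophage list (0 and 1, F13a1 at 1.03; adjusted p = 0.027) higher, each with adjusted p = 0.979 with an estimated correlation. The NRF2 list had a median of -0.04 but an upward camera direction that did not pass, and fry called 0 of the 23 lists. The cytokine call was lost without WT contralateral 24 h (adjusted p = 0.577), Prdx1-/- contralateral 24 h (0.0989), Prdx1-/- ipsilateral 24 h (0.119) or WT ipsilateral 48 h (0.297), and with the 48 h libraries alone (0.546). The antigen presentation call was lost without WT contralateral 48 h (0.0759), WT ipsilateral 48 h (0.277) or Prdx1-/- ipsilateral 48 h (0.452), and the monocyte and macrophage call without WT ipsilateral 24 h (0.185), WT contralateral 48 h (0.445) or Prdx1-/- contralateral 48 h (0.0504). The last call was also lost with list genes of at least 20 CPM alone (0.0654). Without WT ipsilateral 48 h, 3 lists passed in all.

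Within the ipsilateral hemisphere alone, 0 genes passed between labelled genotypes by edgeR, 832 had an unadjusted p under 0.05, and DESeq2 called 5. At 24 h these libraries held 639 CPM (labelled Prdx1-/-) and 594 CPM (labelled WT) of Prdx1. Neither this contrast nor the interaction below therefore measures the effect of Prdx1 loss. The genes with the smallest p were lower interferon genes, Oasl2 (-1.24, SE 0.17, adjusted p = 0.384) and Irf7 (-1.17, SE 0.17, adjusted p = 0.384), with Tnfrsf17 (-1.79), and the higher genes Slc7a5 (0.73, SE 0.12, adjusted p = 0.530), Relt (0.72) and Pilra (0.53). Of the 18 interferon genes 8 were lower adjusted over the list alone (median -0.52), with Xaf1 at -0.80 and Ifit2 at -1.02. Spp1 had a log2 fold change of -0.74 (SE 0.40, adjusted p = 0.811) and Siglech one of -0.55 (SE 0.15, adjusted p = 0.675). Fitted with the 4 ipsilateral libraries alone, 73 genes were higher and 66 lower, and leaving out 1 library of 8 gave 0 to 2 genes. The interaction of genotype and hemisphere, which asks whether the injury response differed between labels, called 0 genes (200 at an unadjusted p under 0.05, 4 by DESeq2, and 11 without the contralateral 48 h library labelled WT). The smallest p belonged to Igkc (5.16), Adm (4.38), Edn1 (1.37), Fabp5 (-1.31, SE 0.24), Hist1h1c (-1.07) and Thbd (-2.49), all at adjusted p = 1.0.

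In monocyte/macrophage-like cells of the injured hemisphere, 381 of 10407 genes tested were higher and 359 lower (edgeR quasi-likelihood test, 4 libraries against 4). The class lay in clusters 4, 8 and 15 in unlike proportions on each side. Of all cells they held 1.70%, 1.65% and 0.96% contralateral and 11.8%, 7.12% and 2.06% ipsilateral (mean of 4 libraries). At 48 h, cluster 15, led by Rsad2 and Ifit3, held 67 of 212 and 82 of 322 contralateral cells of the class (WT and Prdx1-/-), against 266 of 1395 and 109 of 1178 ipsilateral ones. Phlda1 rose by a log2 fold change of 1.65 (SE 0.15, adjusted p = 3.56e-04), Adora2b (an adenosine receptor) by 1.61 (SE 0.13, adjusted p = 3.31e-04), Arg2 (arginase 2) by 1.58 and Crem, a cyclic AMP responsive factor, by 1.56. The largest falls were in Sparc (-3.02, SE 0.28, adjusted p = 0.0017), the interferon-induced gene Ifit3 (-2.004, SE 0.21, adjusted p = 0.0022), Olfml3 (-1.96) and Cx3cr1 (-1.83). Of 18 interferon response genes 6 fell (9 adjusted over the list alone), and of 17 tested NRF2 targets 4 rose (8 adjusted over the list alone). Of 19 tested glycolysis and hypoxia genes 2 rose (4 adjusted over the list alone), and of 18 cytokine genes 2 rose and 2 fell (5 and 3 adjusted over the list alone). Of 18 homeostatic microglia genes 16 fell (18 adjusted over the list alone), with a median of -1.76, and of 18 dissociation and immediate-early genes 4 fell (1 higher and 6 lower adjusted over the list alone). The count was 382 without WT contralateral 24 h, 429 without WT ipsilateral 24 h, 372 without Prdx1-/- ipsilateral 24 h, 338 without Prdx1-/- contralateral 48 h and 452 without Prdx1-/- ipsilateral 48 h. The Arg2 call was lost without either contralateral 24 h library (adjusted p = 0.0535 and 0.0804) or either 48 h library labelled Prdx1-/- (0.0828 and 0.0661), the Ifit3 call with the 48 h libraries alone (0.369), and the Sparc call with doublets kept (-1.53, 0.0714).

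Between labelled genotypes, 2 genes passed in monocyte/macrophage-like cells: the microglial gene Fcrls was lower (-1.40, SE 0.14, adjusted p = 0.0069) and Gm5483, a stefin-like gene of a multigene family and so uncertain, was higher (2.93, SE 0.32, adjusted p = 0.0073). Gm5483 also led a neutrophil-like cluster, and with doublets kept 0 genes passed (Fcrls -1.16, Gm5483 1.16). Fcrls lost its call without WT contralateral 24 h (0.058) or Prdx1-/- ipsilateral 24 h (0.0735), and Gm5483 without any ipsilateral library (0.151, 0.112, 0.195 and 0.370). Cxcr4 (-0.62, adjusted p = 0.0958) and Creb5 (0.90, adjusted p = 0.151) did not pass, and DESeq2 called 8 genes. With the 48 h libraries alone, 197 genes passed.

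In neutrophil-like cells of the injured hemisphere, 167 of 8579 genes tested were higher and 56 lower (edgeR quasi-likelihood test). The class lay in partly different clusters on each side. Of all cells, cluster 10 held 0.133% contralateral and 6.92% ipsilateral, cluster 6 held 1.15% and 11.95%, cluster 11 held 1.74% and 5.52%, and cluster 18 held 0.538% and 1.35% (mean of 4 libraries). Tnf rose by a log2 fold change of 2.24 (SE 0.27, adjusted p = 0.0026), Tnfrsf26 by 2.13, the transcription factor gene Egr3 by 2.05 and the cystine transporter gene Slc7a11 by 2.04 (SE 0.38, adjusted p = 0.0232). Of 17 tested cytokine genes 5 rose (13 adjusted over the list alone, median 1.19), and of 18 tested NRF2 targets 7 rose (8 higher and 1 lower adjusted over the list alone, median 0.63). The largest falls were in Gpr34 (-3.76, SE 0.27, adjusted p = 9.7e-05), Sparc (-3.43), Tmem119 (-3.15) and Cx3cr1 (-2.93). Of the homeostatic microglia genes, 11 of 18 were lower (13 adjusted over the list alone). With the 48 h libraries alone 2 genes passed, and Tnf (adjusted p = 0.0846), Tnfrsf26, Egr3, Slc7a11, Sparc and Tmem119 were not among them. Leaving out 1 library gave 147 genes (WT contralateral 24 h), 17 (WT ipsilateral 24 h), 22 (Prdx1-/- contralateral 24 h), 17 (Prdx1-/- ipsilateral 24 h), 70 (WT contralateral 48 h), 20 (WT ipsilateral 48 h), 115 (Prdx1-/- contralateral 48 h) and 1045 (Prdx1-/- ipsilateral 48 h). The calls of Tnfrsf26, Egr3 and Slc7a11 were each lost without 5 of the 8 libraries, and that of Egr3 with doublets kept (1.40, adjusted p = 0.356). Between labelled genotypes 0 genes passed (138 at an unadjusted p under 0.05, 0 by DESeq2, 8 by edgeR without the low-count filter). Enah (1.89), Ptgir (1.48), Rtp4 (-0.91) and Irf7 (-0.67) had among the smallest p, all at adjusted p = 1.0, and 4 of 16 tested interferon genes were lower adjusted over the list alone.

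In T and NK-like cells, 24 genes were higher and 16 lower on the ipsilateral side of 8456 tested. The class included cluster 23, led by Calca, Trdc and Cpa3. At Leiden resolution 2.0 a cluster of 79 cells led by Calca, Tpsb2, Cma1, Cpa3 and Mcpt4 was left unnamed. The class then went from 56 to 44 cells (contralateral) and stayed at 66 (ipsilateral) at 24 h under the label WT. Under the label Prdx1-/- at 48 h it went from 114 to 101 and from 141 to 129. Its genes were not tested at that resolution. Crem (1.54, SE 0.17, adjusted p = 0.0033), Rgcc (1.40), Rnf125 (1.38) and the lymphocyte receptor gene Gpr18 (1.33) rose, and F11r (-2.63, SE 0.44, adjusted p = 0.0323), Plxdc2 (-2.03), Abi3 (-1.65) and Zfp36 (-1.43) fell. Hemoglobin genes had a median of 4.46, with 1 of 5 higher (5 adjusted over the list alone), and 3 of 18 dissociation and immediate-early genes fell (5 adjusted over the list alone). Of 18 homeostatic microglia genes 1 fell (5 adjusted over the list alone), with a median of -1.99. The count was 76 without WT contralateral 24 h, 11 without WT ipsilateral 24 h, 14 without Prdx1-/- contralateral 24 h, 3 without Prdx1-/- ipsilateral 24 h, 69 without WT ipsilateral 48 h, 4 without Prdx1-/- contralateral 48 h and 13 without Prdx1-/- ipsilateral 48 h. The calls of Rgcc, Rnf125, Gpr18, F11r, Plxdc2 and Abi3 were each lost without at least 1 library (adjusted p up to 0.327). With the stricter cell filter these and Zfp36 did not pass (adjusted p from 0.0726 to 0.768). With doublets kept, Rgcc (1.04), F11r (-1.53), Plxdc2 (-1.58) and Abi3 (-1.05) did not (adjusted p from 0.0581 to 0.245), nor did Plxdc2 with the 48 h libraries alone (0.103). Between labelled genotypes edgeR called 0 genes (303 at an unadjusted p under 0.05, 1 by DESeq2, and 6, 4, 4 and 3 without WT contralateral 24 h, WT ipsilateral 24 h, WT contralateral 48 h and WT ipsilateral 48 h). Cebpd (1.65, adjusted p = 0.609), Osm (0.83), Nt5e (-0.94, adjusted p = 0.609) and Gm9961 (-2.87) had among the smallest p. B-like cells were numerous enough only in the ipsilateral libraries, where edgeR called 0 of 4603 genes (147 at an unadjusted p under 0.05, 0 by DESeq2). Their lowest p values fell to Ifitm3 (-2.47, SE 0.43, adjusted p = 0.501), Ifi27l2a (-0.88, SE 0.16, adjusted p = 0.501), Il7r (1.93) and Nrd1 (0.90), and 3 of 6 tested interferon genes were lower adjusted over the list alone.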

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

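All tests in this part were chosen only after the results they address had been seen. The effect of hemisphere differed between 24 h and 48 h for 7 genes of microglia-like cells (interaction of hemisphere and time, edgeR): H2afv (1.33), Kif23 (2.03), Hacd4 (1.38), Cdkn2c (1.76), Gm26714 (1.82), B930036N10Rik (-1.50) and Acvrl1 (-1.10). H2afv and Kif23, genes of chromatin and cell division, were lower on the ipsilateral side at 24 h and higher at 48 h (Kif23 at 3.8 and 1.4 CPM, then 13.6 and 22.6 CPM, contralateral and ipsilateral, under the label WT). In sums of T and NK-like cells the effect of labelled genotype differed between times for 1 gene, Arg1 (-5.81), which stood at 262 and 156 CPM in the 24 h libraries labelled Prdx1-/- and belongs to the monocyte and macrophage list. In the same contrast that list had a median of -1.64 (1 of 12 tested genes lower, 1 adjusted over the list alone). The homeostatic microglia list had a median of -2.74 (0 passed, 6 of 18 lower adjusted over the list alone) and the neutrophil list one of 4.95 (0 passed, 0 adjusted over the list alone). In monocyte/macrophage-like cells it differed for 1 gene, Prdx1 itself (-5.74).

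Prdx1 transcripts were present in both 24 h libraries labelled Prdx1-/-. Free RNA is argued against by the ipsilateral library, where Prdx1 CPM was 12.04 times higher in microglia-like than in neutrophil-like cells. A wrong label on the whole contralateral library is argued against by its 23.53% of thinned microglia-like cells with a Prdx1 UMI, between the 68.8% of the matched library labelled WT and the 3.31% at 48 h. For the ipsilateral library a wrong label stays open. Against the matched library labelled WT, its share was lower in microglia-like (37.9% against 56.7%) and monocyte/macrophage-like cells (52.5% against 61.7%). It was higher in cluster 7 (67.2% against 54.5%) and T and NK-like cells (51.1% against 41.3%, intervals overlapping). Libraries that mix cells with and without Prdx1 may account for the transcripts in both libraries. Prdx1 had more cells at zero there than at least 91.8% of genes of similar level in both classes tested (microglia-like and monocyte/macrophage-like). In the 48 h libraries labelled WT that figure was at most 77.0%. The ipsilateral 24 h library labelled WT, where 54.5% of thinned cluster 7 cells had a Prdx1 UMI, reached 93.8% and 90.2%. The contralateral 24 h library labelled WT stood at 42.0% and 21.1%, so under that label the excess of zeros was seen in the ipsilateral library only. The labels do not say whether both hemispheres came from the same animals. Whether animals were pooled, the deletion was mosaic or cells of different libraries were mixed was not tested.

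Svbp and Spata6, both on chromosome 4 with Prdx1, were among the 7 genotype calls in microglia-like cells. DNA of another strain or the edited locus around Prdx1 could change nearby genes. Within 20 Mb of Prdx1 lay 2 of the 7 against 0.17 expected, 11.45 times (95% counting interval 1.42 to 42.5), but these genes prompted the test and are no separate evidence. In the same window lay 15 of 392 placed calls in the 48 h libraries alone, 1.5 times the 9.99 expected (95% counting interval 0.84 to 2.48). Svbp and Spata6 were among these 15, so this count is not fully separate either. The second interval covers both no excess and the doubling set as the bound, so a local effect and an effect of Prdx1 loss cannot be told apart for these genes.

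Microglial transcripts were lower on the ipsilateral side in classes that should hold few of them. Free RNA from microglia-like cells, which were fewer there, is a candidate explanation: the homeostatic list had median log2 fold changes of -1.66 in neutrophil-like, -1.76 in monocyte/macrophage-like and -1.99 in T and NK-like cells. Its genes stood at a median of 4.44% (contralateral) and 2.08% (ipsilateral) of the microglia-like level in neutrophil-like cells. The same values were 5.02% and 3.32% in monocyte/macrophage-like cells and 9.09% and 3.28% in T and NK-like cells. The list also fell within microglia-like cells (median -1.10), so these falls do not reflect the number of microglia-like cells alone. Cells misplaced between classes and real expression by macrophages stay open.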

How the results depend on the processing

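The 48 h libraries alone were an alternative chosen only after the results were seen; the others here were planned. In microglia-like cells, a paired fit of hemispheres of the same labelled genotype and time gave 6308 genes, and a block for each hemisphere and time gave 132 for genotype. The labels do not say which animals the hemispheres came from. In microglia-like cells the hemisphere count of 6220 was 3543 at 48 h alone and 4598 to 6114 with 1 library left out. Of 72 named genes called there, 58 were called under all alternatives run, against 14 of 37 for time and 0 of 7 for genotype. The genotype count of 7 became 150 (DESeq2), 24 (no low-count filter), 0 (stricter cell filter), 0 (doublets kept), 0 (class by marker score), 400 (48 h alone) and 0 to 24 (1 library left out). Genotype in the ipsilateral hemisphere went from 0 to 5 (DESeq2), 3 (no filter), 139 (ipsilateral libraries alone) and 0 to 2 (1 left out). The interaction went from 0 to 4 (DESeq2) and 0 to 11 (1 left out). The time count of 1643 was 758 with the stricter cell filter and 342 to 1710 with 1 left out. Genes of the other classes were not tested under other ways of assigning cells to classes, so their counts below say nothing about that choice. For T and NK-like cells, hemisphere gave 93 (no filter), 3 (stricter), 82 (48 h alone) and 3 to 76 (1 left out), and genotype 1 (DESeq2), 1 (no filter), 54 (48 h alone) and 0 to 6. Monocyte/macrophage-like cells gave 1117 (no filter) and 338 to 648 for hemisphere, and 8 (DESeq2), 21 (no filter), 0 (doublets kept), 197 (48 h alone) and 0 to 3 for genotype. Neutrophil-like cells gave 389 (DESeq2), 887 (no filter), 2 (48 h alone) and 17 to 1045 for hemisphere, and 8 (no filter) for genotype. B-like cells gave 13 (no filter), 3 (stricter) and 8 (doublets kept); leaving out 1 of their 4 libraries leaves no residual degree of freedom and was not run. Gene list calls went to 0 with an estimated correlation for hemisphere and for genotype, and to 0 by fry for genotype, where 3 to 7 lists were called with 1 library left out. Class share calls ranged from 2 to 4 for hemisphere with 1 left out. 2 directions turned: the microglia-like share between genotypes ran from -0.54 to 0.14 with 1 library left out (0.14 without the ipsilateral 24 h one labelled WT), and the cytokine list median between genotypes from -0.0112 (without the contralateral 24 h one labelled WT) to 0.44. Of the values of single genes, classes and lists, 2917 kept direction and side of the threshold, 335 fell short of it and 61 newly passed. Fewer libraries lower the residual degrees of freedom; beyond that the cause was not tested. Classes with few cells per library, such as the 45 neutrophil-like cells of the contralateral 24 h library labelled Prdx1-/-, limit what could be detected.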

Other observations

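The tests of other splits reported in this part were all chosen only after the results had been seen. Among the clusters left unnamed, cluster 12, led by Fabp5, Pf4 and the lipid-associated gene Gpnmb, held 15.6% of cells in the ipsilateral 48 h library labelled WT and 6.50% in that labelled Prdx1-/-, against 0.551% and 1.05% at 24 h. Cluster 9, led by H2-Ab1, Cd74 and Cd209a, held 11.4% and 4.48% in the same 48 h libraries and 2.85% and 7.06% in the 24 h ones. Cluster 20, led by the granule genes Elane, Mpo, Ctsg and Prtn3, held 3.59% of the ipsilateral 48 h library labelled Prdx1-/- and at most 0.552% of any other library. These shares come from 1 library each and were not tested between groups.

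The 8 libraries can be split in 35 ways into 4 against 4. For hemisphere, only the real split gave so large a count for microglia-like genes (1 split, 6220 genes, highest other 211). The same held for monocyte/macrophage-like genes (1 split, 740, highest other 59) and class shares (1 split, 3 classes, highest other 0). In the other splits any hemisphere effect stays in the spread and can lower their counts, so the size of the gap to them is hard to read. First of 35 is the best rank possible, and libraries that differ by genotype and time are not interchangeable. This ranking therefore does not exclude chance. The splits that gave 211 and 59 genes were that by time, itself a factor of the design. Nor can chance be excluded for neutrophil-like genes (2 splits, 223, highest other 824), T and NK-like genes (2 splits, 40, highest other 44) or gene lists (11 splits, 13, highest other 14). For labelled genotype it cannot be excluded for microglia-like genes (4 splits; 7, highest other 5866), monocyte/macrophage-like genes (8 splits; 2, highest other 768) or gene lists (25 splits; 5, highest other 13). The real count was 0 for class shares (highest other 4), neutrophil-like genes (highest other 368) and T and NK-like genes (highest other 66), where all 35 splits are as large by definition and say nothing about chance. The splits that gave 5866 genes, 768 genes, 4 class shares and 13 lists were that by hemisphere. The splits set beside genotype thus hold a real structure of the samples and are no picture of no change.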
